A study of Homo sapiens with 12 samples.

How the data were processed

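Gene expression was measured on 12 Affymetrix whole-transcript arrays, 1 per sample, in U-87MG cells, an established human glioblastoma line, carrying a control shRNA (shCtrl). Per the labels, cells were seeded in six-well plates, treated for 24 h with the solvent DMSO, with 100 nM FICZ (6-formylindolo[3,2-b]carbazole) or with 50 µM kynurenic acid (KynA), and total RNA was labelled with biotin as single-stranded cDNA. Each of the 3 groups held 4 samples that the labels call biological replicates. Whether they came from separate cultures or days is not given in the sources used here, so p-values measure the spread between these samples, which may be partly technical.

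The deposited values are log2 signals that the authors made with RMA in oligo, per the submitters' processing notes. The versions and the array annotation are not given in the sources used here. The table held 15759 transcript clusters with values from 3.005 to 13.82. Row means ran from 6.496 to 13.68, so dim transcripts are missing from the table, and the rule that left them out is not given in the sources used here. Array medians lay between 8.30 and 8.33.

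Gene symbols came from the platform annotation paired with the table, which can be old, and were not updated. Of the transcript clusters, 13577 had 1 symbol, 744 had several and 1438 had none. The clusters with 1 symbol stood for 13530 genes, and for the 45 genes with several clusters the one with the highest mean over all arrays was kept. A gene was tested if it lay above the 25th percentile of its array (7.687 to 7.743) in at least 4 arrays, which left 10807 genes. CYP1A1 had no cluster with a symbol of its own and was not analysed here. Clusters with several or no symbols were tested separately and are given only in the closing section.

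The model was limma's group-means fit over all 12 arrays, with 9 residual and 5.19 prior degrees of freedom, so that the groups shared 1 estimate of the spread. Contrasts were FICZ against DMSO, KynA against DMSO and FICZ against KynA, tested two-sided with limma's moderated test and Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. Fold changes are given as log2 differences ± SE with n = 4 arrays per group. Arrays carry no read depth, and their number limits the precision; the median SE of a log2 difference was 0.106.

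There were 38 gene lists, of which 35 had at least 5 tested members. They were tested against the other genes with limma's camera at its preset correlation of 0.01, adjusted over the lists of a contrast. Camera with a correlation estimated within each list was run beside it, as was fry, which asks whether the genes of a list move one way on balance. The mean of each list per array was also compared by a two-sided exact permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286. Counts of members are given over all genes tested and adjusted over the list alone.

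The groups, lists, contrasts, filter, alternatives and rule for named genes were fixed before the data were examined. The rule took, for each ligand against DMSO, the 10 largest rises and the 10 largest falls among genes that passed with all 4 treated arrays on that side of the DMSO mean, or all that passed if fewer. For FICZ against KynA it took the 5 largest in each direction. It always took CYP1A1, CYP1B1, AHRR, TIPARP, NQO1, ALDH3A1 and AHR. For each list described it took up to 4 members with the smallest p. Genes named outside the rule are said to have been chosen after their values were seen.

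Both ligands were compared with the same DMSO arrays. Their overlap and correlation were therefore set beside 100 simulations of unchanged groups against those arrays, the overlap of independent lists, and values with the DMSO arrays split 2 and 2 in all 6 ways.

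The fit was tested on simulated data with the layout of FICZ against DMSO. Among 10807 genes, it recovered 59 of 100 genes changed by 0.5 and 97 of 100 changed by 1 on the log2 scale, with 6 false calls. A list shifted by 0.25 in simulated KynA arrays was recovered against DMSO with 0 of the other lists called. The simulated genes were drawn independently of each other. In the real data the correlation estimated within a list reached 0.443, for the histones. The simulation therefore does not show how often lists of correlated genes are called falsely.

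Alternatives were arrays centred on their median, cyclic loess, no filter, a filter at the 50th percentile, the mean of the clusters of a gene, eBayes with trend and robust, array weights, only the groups compared, the replicate number as a block, and leaving out each array. Camera takes no random block, so lists under that setting were tested with cameraPR on the moderated statistics. The tools were R 4.3.3 with limma 3.58.1 and data.table, version 1.17.8, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 for the plots.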

Results

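The series profiled shCtrl U-87MG glioblastoma cells after 24 h with FICZ, KynA or DMSO, with 4 arrays per group, to describe expression after activation of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor. FICZ is a tryptophan photoproduct and a potent AHR ligand, and KynA is a tryptophan metabolite of the kynurenine pathway. The doses differed, at 100 nM FICZ and 50 µM KynA. Correlations between arrays ran from 0.940 to 0.977, and no 2 arrays were duplicates. The mean SD within a group was 0.187 on the log2 scale. Array FICZ 4 stood apart. It had the highest score on the first principal component (0.729, with 24.6% of the variance; the next was FICZ 2 at 0.411) and the lowest array weight (0.551).

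FICZ against DMSO asked which genes changed after 24 h with this ligand. The largest rise was in SLC16A6, a member of the monocarboxylate transporter family, by 2.51 ± 0.139 on the log2 scale (SE, n = 4; 5.70-fold; limma adjusted p = 3.81e-07), from 7.416 ± 0.322 to 9.927 ± 0.0547 (SD, n = 4). The neuronal pentraxin NPTX1 rose by 2.22 ± 0.227 (4.65-fold; adjusted p = 0.000413) and the cytokine IL1B by 2.20 ± 0.256 (4.60-fold; adjusted p = 0.000949). SECTM1 rose by 1.52 ± 0.144 (adjusted p = 0.000231), the secreted glycoprotein STC2 by 1.05 ± 0.137 (adjusted p = 0.00179) and the collagenase MMP1 by 1.05 ± 0.154 (adjusted p = 0.00459). With DMSO, the means of SLC16A6, NPTX1 (6.718), IL1B (7.641), SECTM1 (7.155) and MMP1 (7.335) lay below the filter values of 7.687 to 7.743. These genes were dim without FICZ, which limits the precision of their fold changes. The falls were smaller, and some ended among dim signals. With FICZ the means of COL6A5 (6.956), CCT6P3 (7.58) and ID3 (7.683) lay below those filter values, which limits the measure of their falls. MEST, an imprinted gene, fell by 0.83 ± 0.119 (adjusted p = 0.0039). ID3, an inhibitor of basic helix-loop-helix transcription factors, fell by 0.69 ± 0.117 (adjusted p = 0.0122; DMSO 4 lay above the other DMSO arrays), and the chromatin protein HMGB2 by 0.55 ± 0.0913 (adjusted p = 0.0117). All 4 FICZ arrays lay beyond the DMSO mean for each of these genes, which the rule for named genes required.

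In total 92 of 10807 genes changed with FICZ, 65 higher and 27 lower, of which 11 changed at least 2-fold. At an unadjusted p under 0.05 there were 1572 genes, 637 higher and 935 lower. The count depended on single arrays. It was 42 without DMSO 1, 57 without DMSO 2, 44 without DMSO 3 and 49 without DMSO 4. Without FICZ 2 it was 44, and without FICZ 4 it was 42. In the 12 fits that left out an array, from 41 (without DMSO 1) to 77 (without KynA 2) of the 92 genes kept their call. Each of the 92 kept its sign in every fit, which their selection by a small p made likely beforehand. The count was 43 with only the 8 arrays of these groups and 140 with a trended, robust variance. With those 8 arrays ID3 (adjusted p = 0.0511), HMGB2 (0.0512) and HIST1H1B (0.0504) no longer passed.

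Other genes among the largest changes passed less firmly. MIR155HG, a microRNA host gene, rose by 1.17 ± 0.223, and lost its call without DMSO 1, DMSO 2, DMSO 4, FICZ 2 or FICZ 4 (highest adjusted p 0.0877, without DMSO 4). The matrix glycoprotein gene THBS1 rose by 1.10 ± 0.236 and kept its call in 2 of 12 fits, without FICZ 2 or KynA 2 (highest adjusted p 0.116, without DMSO 4). The collagen gene COL6A5 fell by 0.88 ± 0.18, with DMSO 2 far below the other DMSO arrays, and kept its call in 4 fits, without DMSO 2, FICZ 3, KynA 1 or KynA 2 (highest 0.116, without DMSO 4). The pseudogene CCT6P3, whose probes may be shared with its relatives, fell by 0.81 ± 0.167 and kept its call in 3, without FICZ 1, KynA 1 or KynA 3 (0.116, without DMSO 4). The plexin gene PLXNA2 fell by 0.60 ± 0.13 and kept its call in 1, without KynA 2 (0.137, without DMSO 1). POGK fell by 0.57 ± 0.106, with FICZ 1 below the other FICZ arrays, and lost its call without DMSO 2, DMSO 3, FICZ 1, FICZ 2 or FICZ 4 (0.0868, without DMSO 3). AKR7A2, an aldo-keto reductase, fell by 0.56 ± 0.106 and lost its call without DMSO 1, DMSO 3, DMSO 4, FICZ 1 or FICZ 4 (0.0853, without DMSO 4). DCP1B, an mRNA decapping factor, fell by 0.53 ± 0.112 and kept its call in 2, without DMSO 3 or KynA 4 (0.116, without DMSO 4). Leaving out FICZ 4 ended the call of each of these 8 genes. THBS1, COL6A5, CCT6P3, PLXNA2 and DCP1B also lost it without a filter (adjusted p 0.0588 to 0.0711), THBS1, CCT6P3, PLXNA2 and DCP1B with array weights (0.0518 to 0.0635), and THBS1, COL6A5, PLXNA2, AKR7A2 and DCP1B with only the 8 arrays compared (0.0502 to 0.0934). PLXNA2 also lost it with arrays centred on their median (0.0539).

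Both lists of genes known to respond to AHR were called higher with FICZ. In the AHR target battery, 3 of 7 tested members rose, over all genes and adjusted over the list alone. TIPARP, which codes for a feedback inhibitor of AHR, rose by 1.21 ± 0.135 (2.31-fold; adjusted p = 0.000659), the cytochrome P450 gene CYP1B1 by 1.07 ± 0.165 (2.10-fold; 0.00629) and the AHR repressor AHRR by 0.97 ± 0.147 (1.96-fold; 0.00565). NQO1 (0.09 ± 0.13, adjusted p = 0.783) and ALDH3A1 (−0.11 ± 0.142, 0.753) did not pass. Outside the battery, AHR itself (−0.10 ± 0.0758, adjusted p = 0.586) did not pass either. The battery shifted upward against other genes (camera adjusted p = 3.70e-06). Its adjusted p was 0.127 with an estimated correlation and 0.00842 by fry. The battery mean was above the DMSO mean in 4 of 4 FICZ arrays (exact permutation p = 0.0286, or 0.167 adjusted over the 35 lists). Among 13 other AHR-responsive genes, 4 rose over all genes and 8 adjusted over the list alone. These 4 were IL1B, STC2, MMP1 and the growth factor gene EREG, at 0.91 ± 0.125 (adjusted p = 0.00276). That list's shift (adjusted p = 2.70e-10) held with an estimated correlation (adjusted p = 0.00289).

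**Figure D1:**
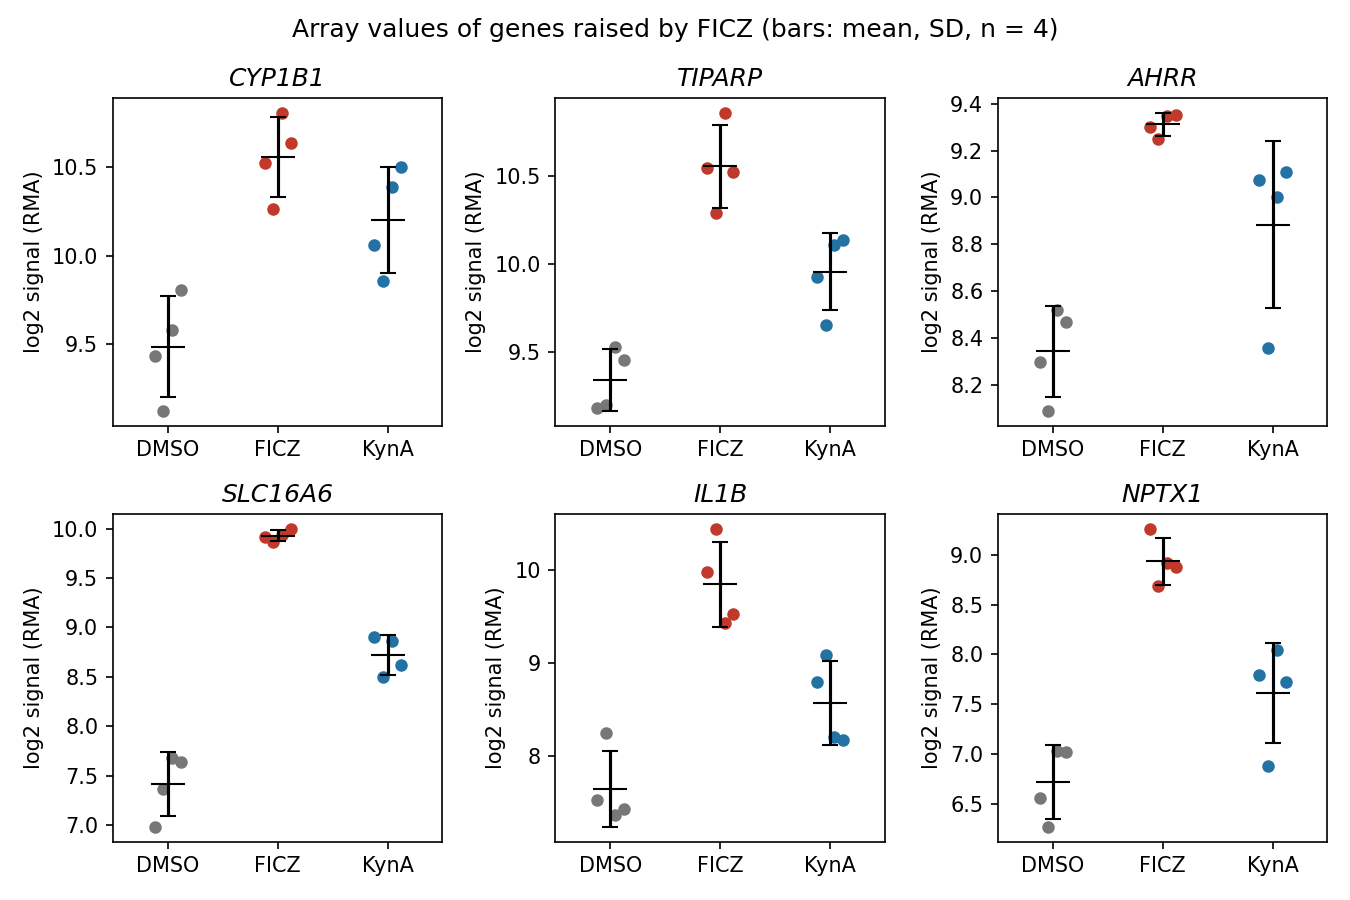
Log2 RMA signal of CYP1B1, TIPARP, AHRR, SLC16A6, IL1B and NPTX1 in each array by group; points are arrays, and bars give the mean and SD of n = 4. SLC16A6 averaged 7.416 with DMSO, 8.722 with KynA and 9.927 with FICZ.

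Cell cycle genes were lower as groups with FICZ, by small amounts per gene. Of 29 G2/M and mitosis genes none passed over all genes tested, 19 fell adjusted over the list alone, and all 29 had negative values, with a median of −0.25. Values were −0.34 for the spindle factor gene TPX2 (adjusted p = 0.0581; DMSO 1 below the other DMSO arrays), −0.34 for BIRC5 (0.0629), −0.31 for CDC20 (0.0888) and −0.36 for the cyclin gene CCNB2 (0.109; DMSO 4 below the other DMSO arrays). TPX2 and BIRC5 passed under the stricter filter (0.0343 and 0.0402), and TPX2, BIRC5 and CDC20 with a trended, robust variance (0.0123, 0.0421 and 0.0291). The list shifted downward (camera adjusted p = 8.89e-13). Its adjusted p was 0.096 with an estimated correlation and 0.00152 by fry. Of 28 G1/S and replication genes none passed over all genes, 12 fell adjusted over the list alone and all 28 had negative values, among them RFC3 at −0.32 (adjusted p = 0.0548, and 0.0312 under the stricter filter and 0.0381 with a trended, robust variance) and GINS2 at −0.46 (0.0917). That list also shifted downward (camera adjusted p = 4.85e-09). Its adjusted p was 0.163 with an estimated correlation and 0.00918 by fry. Both list means were below the DMSO mean in 4 of 4 FICZ arrays (exact permutation p = 0.0286 each; 0.167 adjusted over the lists), with G2/M array means of −0.197, −0.237 and −0.188 and the lowest, −0.395, in FICZ 4.

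Hypoxia-responsive and inflammatory lists shifted upward. In the hypoxia response list 3 of 26 genes rose over all genes, and 5 adjusted over the list alone. The angiogenic factor gene VEGFA rose by 0.52 ± 0.0801 (adjusted p = 0.00626), hexokinase 2 (HK2) by 0.55 ± 0.103 (0.0242) and the glucose transporter SLC2A1 by 0.51 ± 0.102 (0.0336; DMSO 2 above the other DMSO arrays). HK2 kept its call in 7 of 12 fits that left out 1 array and SLC2A1 in 6, and both lost it without DMSO 1, DMSO 4 or FICZ 4, with highest adjusted p of 0.0809 and 0.115 without DMSO 4. HK2 also lost it without DMSO 2 or FICZ 1 and with only the 8 arrays compared (0.0762), and SLC2A1 without DMSO 3, FICZ 2 or FICZ 3 and without a filter (0.0536). The hypoxia shift had a camera adjusted p of 6.13e-06, an adjusted p = 0.333 with an estimated correlation and 0.169 by fry. Its exact permutation p was 0.0571 (0.222 adjusted). In the NF-kB and cytokine list 2 of 17 rose over all genes, IL1B and the chemokine CCL2 (0.93 ± 0.147; adjusted p = 0.0078). Adjusted over the list alone, 7 rose and 1 fell. The list's camera adjusted p was 2.54e-04, with adjusted p = 0.163 with an estimated correlation and 0.0375 by fry.

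**Figure D2:**
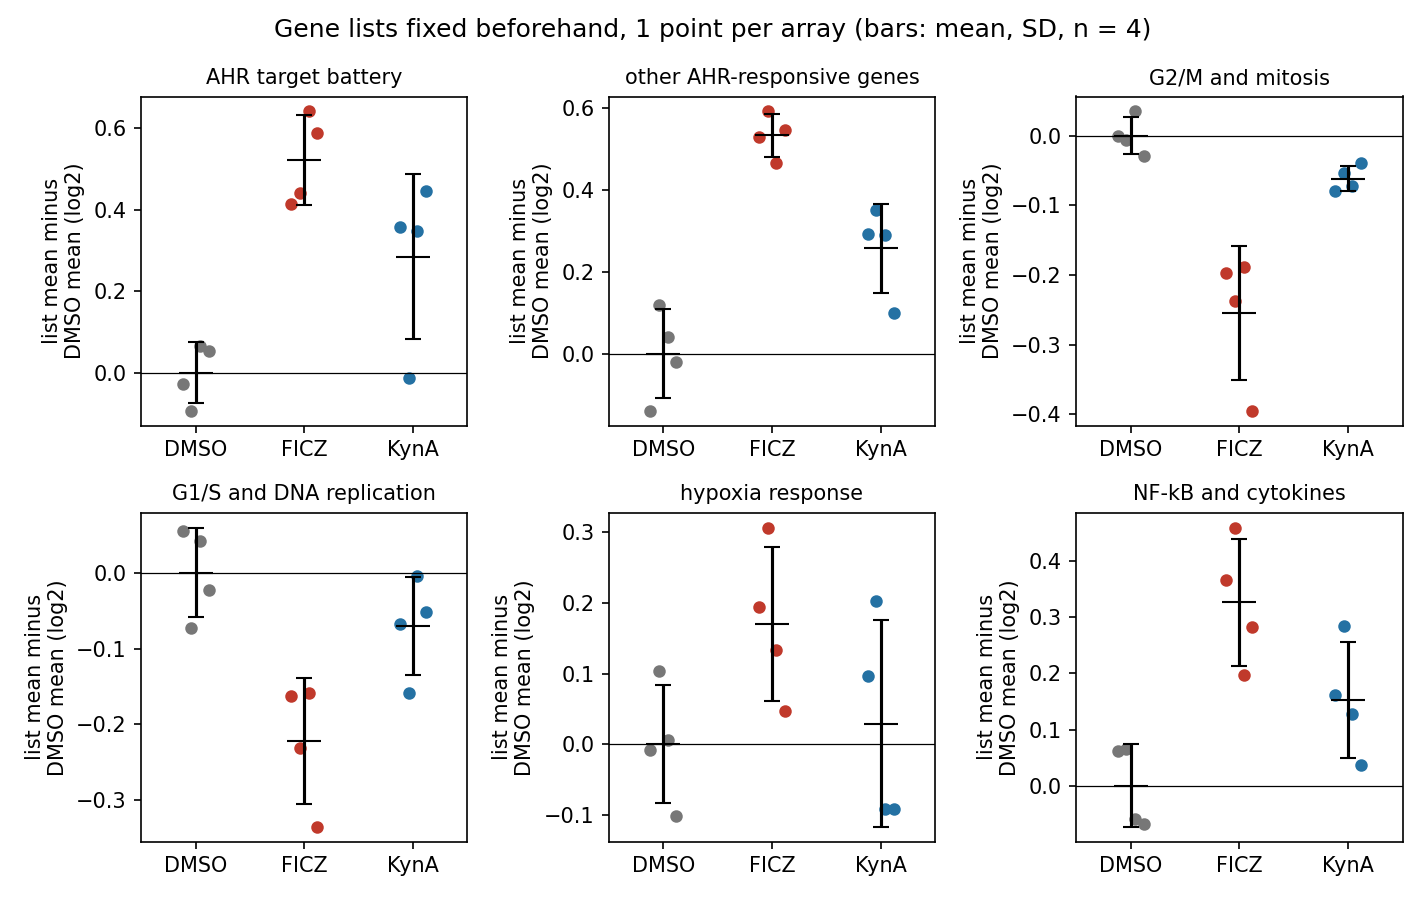
Mean of 6 gene lists in each array as a log2 difference from the DMSO mean; points are arrays, and bars give the mean and SD of n = 4. The G2/M list lay between −0.395 and −0.188 in the FICZ arrays and between −0.0799 and −0.0391 in the KynA arrays.

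A further 5 lists were called with FICZ on few or no single genes. In the matrix list 1 of 30 genes rose, MMP1 (adjusted p = 0.011; adjusted p = 0.581 with an estimated correlation). Of the replication-dependent histones 1 of 6 fell, HIST1H1B at −0.53 ± 0.0917, whose probes may be shared within the family (0.00254; adjusted p = 0.333 with an estimated correlation). None of 19 ribosomal protein genes passed, and their shift was downward (0.0189; adjusted p = 0.629 with an estimated correlation). Of the marker lists of other cell types, 2 were called higher. Of 6 myeloid and microglia markers 1 rose, TMEM119, by 0.63 ± 0.124, and of 7 endothelial markers 1 rose, KDR, by 0.48 ± 0.0939 (2 adjusted over the list alone). These lists had adjusted p = 0.011 and 0.0353, and adjusted p = 0.333 and 0.163 with an estimated correlation. TMEM119 was highest in FICZ 4 and lost its call without DMSO 1, DMSO 2, DMSO 3 (0.105), FICZ 2 or FICZ 4 (0.0761), without a filter (0.0515) and with only the 8 arrays compared (0.067). KDR was highest in FICZ 3 and lost its call without DMSO 1, DMSO 2, DMSO 3 (0.0868), FICZ 2 or FICZ 3 (0.0525), and with only the 8 arrays compared (0.0531).

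FICZ 4 had the most extreme mean in 3 of these lists, at −0.286 for ribosomal proteins (other FICZ arrays −0.0269 to −0.0939), −0.494 for histones (−0.0799 to −0.304) and 0.596 for myeloid markers (0.083 to 0.363). The ribosomal call was lost without FICZ 4 (adjusted p = 0.336), DMSO 1 (0.061) or DMSO 2 (0.0672), under cyclic loess (0.142) and with array weights (0.0873). The myeloid call was lost without FICZ 4 (0.092) or DMSO 4 (0.0784), and without the filter on dim genes (0.0601). The matrix call was lost without DMSO 2 (0.0672), FICZ 1 (0.126) or FICZ 3 (0.0802), and under the stricter filter (0.0816). The endothelial call was lost without DMSO 2 (0.0672), FICZ 1 (0.151) or FICZ 3 (0.0521), under cyclic loess (0.0571) and with a trended, robust variance (0.0689).

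KynA against DMSO asked the same of the metabolite. SLC16A6 rose by 1.31 ± 0.139 (SE, n = 4; 2.47-fold; limma adjusted p = 0.002), in 4 of 4 KynA arrays, and was the only 1 of 10807 genes that passed, while 366 had an unadjusted p under 0.05, fewer than the 540 that chance gives. The AHR targets CYP1B1 (0.71 ± 0.165, adjusted p = 0.494), TIPARP (0.61 ± 0.135, 0.469) and AHRR (0.54 ± 0.147, 0.854) had positive values that did not pass, as did STC2 (0.76 ± 0.137, 0.284), CCL2 (0.73 ± 0.147, 0.284) and IL1B (0.92 ± 0.256, 0.923). NQO1 (−0.01), ALDH3A1 (0.03) and AHR (0.01) had adjusted p = 1 each. A second gene passed without DMSO 1 (CCL2, count 2), without KynA 2 (AHRR, count 2), where AHRR was lowest, and with a trended, robust variance. With the replicate number as a block 6 genes passed. They were SLC16A6, IL1B (limma adjusted p = 0.00737), CYP1B1 (0.0134), STC2 (0.0216), TIPARP (0.0333) and CCL2 (0.0333). The labels do not say whether equal numbers mark a shared culture or day.

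Both AHR lists were called higher with KynA, each at adjusted p = 3.91e-05 by camera. The adjusted p with an estimated correlation was 0.267 for the battery and 0.0334 for the other AHR-responsive genes, and by fry 0.317 and 0.0845. Of the 7 battery genes none passed over all genes and 4 rose adjusted over the list alone. Of the 13 other AHR-responsive genes none passed and 4 rose adjusted over the list alone. The NF-kB list (0.0214) and the matrix list (0.0218) were called higher, and the G1/S list (0.00639) and G2/M list (0.0214) lower, with no member passing over all genes in any of them and 2 NF-kB genes adjusted over the list alone. With an estimated correlation their adjusted p was 0.636 for NF-kB and 0.746 for the matrix, G1/S and G2/M lists. Each of these 4 calls was lost without some single arrays: G1/S without DMSO 1 (0.0686), DMSO 3 (0.0749) or KynA 2 (0.252), and G2/M without DMSO 2 (0.0683), DMSO 3 (0.101), KynA 1 (0.117) or KynA 3 (0.0551). NF-kB was lost without DMSO 3 (0.101), DMSO 4 (0.118) or KynA 2 (0.252), and matrix without DMSO 2 (0.204), DMSO 4 (0.0635) or KynA 4 (0.434). Under the stricter filter both had adjusted p = 0.125, and without a filter NF-kB had 0.098. The G2/M mean was below the DMSO mean in 4 of 4 KynA arrays (exact permutation p = 0.0286; 0.499 adjusted over the lists).

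FICZ against KynA asked whether the ligands differed, at unequal doses. SLC16A6 was higher with FICZ by 1.20 (95% interval 0.907 to 1.5; 2.31-fold; limma adjusted p = 0.00533), and was the 1 gene of 10807 that passed, with 901 at an unadjusted p under 0.05; 2 genes passed without the filter on dim genes. Differences were 0.35 for CYP1B1 (interval 0.00077 to 0.709; adjusted p = 0.596), 0.60 for TIPARP (0.308 to 0.884; 0.271) and 0.43 for AHRR (0.114 to 0.742; 0.475). IL1B differed by 1.28 (0.732 to 1.83; adjusted p = 0.185) and NPTX1 by 1.32 (0.835 to 1.81; 0.117), neither of which passed over all genes. NQO1 differed by 0.10 (−0.175 to 0.381), ALDH3A1 by −0.14 (−0.449 to 0.161) and AHR by −0.11 (−0.271 to 0.0539). With the replicate number as a block 6 genes passed. Among them were IL1B (limma adjusted p = 0.000365), NPTX1 (0.0135), SECTM1 (0.0487) and TIPARP (0.0487).

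As groups, 8 lists differed between the ligands. Lists that were higher with FICZ were the other AHR-responsive genes (camera adjusted p = 9.27e-07; adjusted p = 0.0142 with an estimated correlation; 5 of 13 adjusted over the list alone), hypoxia (2.59e-06), the AHR battery (0.00384; 2 of 7 adjusted over the list alone) and NF-kB (0.00816). With an estimated correlation the last 3 had adjusted p = 0.363. Lower with FICZ were the G2/M list (2.51e-11; adjusted p = 0.134 with an estimated correlation), G1/S (2.96e-06) and histones (0.0015), both with adjusted p = 0.363 with an estimated correlation, and ribosomal proteins (0.0227; adjusted p = 0.744). No member of these 8 lists passed over all genes. The battery call was lost without KynA 2 (adjusted p = 0.075), NF-kB without FICZ 2 (0.072) or KynA 4 (0.0514) and under the stricter filter (0.0888). The ribosomal call was lost without FICZ 3 (0.0556), FICZ 4 (0.615) or KynA 1 (0.0895), under cyclic loess (0.106) and with array weights (0.122).

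Both ligands were compared with the same DMSO arrays. SLC16A6 was the 1 gene called in both, higher in each, against 0.00602 for independent lists. At an unadjusted p under 0.05 in both, 119 genes were higher with each ligand and 75 lower, against a mean of 141 in both directions together (highest 678) in 100 simulations of unchanged groups. Across genes, which are not independent replicates, the log2 changes had r = 0.604 and rho = 0.542, against a simulated mean r of 0.507 (0.076 to 0.769). The covariance was 0.0139, and 0.00378 above the simulated mean of 0.0101. With the DMSO arrays split between the comparisons r was 0.205, within the simulated −0.362 to 0.362.

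**Figure D3:**
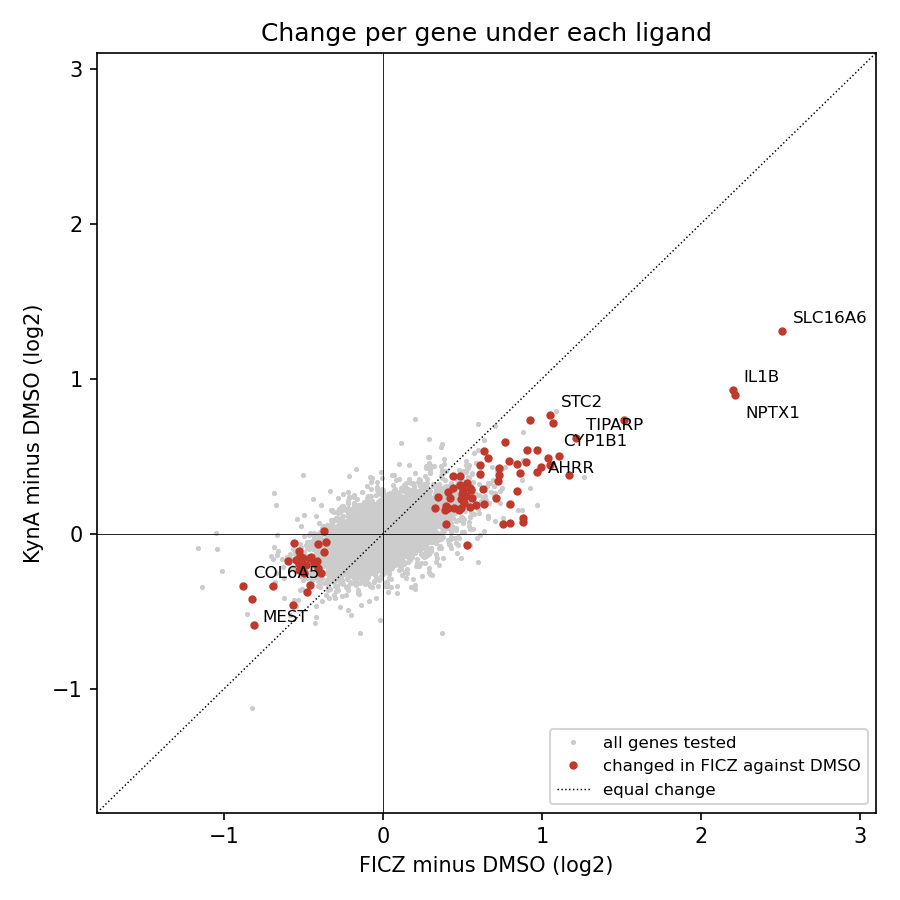
Log2 change of each of 10807 genes with FICZ (x axis) and KynA (y axis) against the same DMSO arrays; red points are the 92 genes changed with FICZ and the dotted line marks equal change. SLC16A6 lies at 2.51 and 1.31, and r across genes was 0.604.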

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

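Among the tests in this part, the same-sign test of the genes that changed most with FICZ was chosen only after the result was seen. The patterns themselves were found in these same arrays, so the tests of them are not independent of how they were found.

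The first pattern is that cell cycle genes were lower in FICZ arrays, with 29 of 29 G2/M genes and 28 of 28 G1/S genes below 0, none of which passed over all genes, and adjusted p = 0.096 and 0.163 with an estimated correlation. Array FICZ 4, which stood apart, is argued against as the whole source, because the G2/M shift had a camera adjusted p of 5.17e-11 without it and the other 3 FICZ arrays lay below the DMSO mean. Growth differences of the size seen among the DMSO wells are argued against for the G2/M list. Its means lay between −0.395 and −0.188 in the FICZ arrays and between −0.029 and 0.035 in the DMSO arrays. The exact permutation p was 0.0286, the smallest 4 against 4 arrays can give (0.167 adjusted over the lists). The FICZ arrays differed more among themselves than the DMSO arrays did, so growth differences of that larger size stay open. For G2/M the KynA arrays also lay below the DMSO arrays, between −0.0799 and −0.0391 (exact permutation p = 0.0286, or 0.499 adjusted). For G1/S, KynA 2 (−0.159) lay level with FICZ 3 (−0.158) and FICZ 1 (−0.162), and the other KynA arrays lay between −0.0678 and −0.00392. A response of the cell cycle to FICZ may account for the lower values, as a hypothesis found and tested on the same arrays, and seeding or handling of the FICZ wells as a group cannot be excluded by the design.

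The second pattern is that the hypoxia response list shifted upward in FICZ arrays, with 3 of 26 genes passing and the call lost with an estimated correlation (adjusted p = 0.333) and by fry (0.169). FICZ 4 is argued against as the source: without it the camera adjusted p was 1.36e-07, and in FICZ 4 itself the list mean was the lowest of the FICZ arrays, at 0.0473. Differences between wells that occur in every group stay open, since DMSO 2 reached 0.103 and the exact permutation p was 0.0571. That test did not pair arrays by replicate number. In order of number the DMSO means were −0.0075, 0.103, 0.00582 and −0.101. The FICZ means were 0.194, 0.306, 0.133 and 0.0473, each above the DMSO mean of its number. The KynA means were 0.0971, 0.203, −0.0911 and −0.0919, so number 2 was highest and number 4 lowest in each group. The labels do not say what the numbers share, and a paired difference was not tested. A biological response to FICZ also stays open, and the pattern could come from either.

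The third pattern is that KynA changes ran parallel to FICZ changes across genes. The correlation of 0.604 may come in part from the shared DMSO arrays. With these arrays split, so that the comparisons shared none, the mean correlation was 0.205. Simulated unchanged groups, split the same way, had a mean of 0.0235 and a highest value of 0.362. Differences between few arrays can therefore reach 0.205. The simulated controls could hold FICZ 4, whose root mean square distance from its group mean was 0.204, against 0.142 to 0.161 in DMSO arrays. The simulated range may therefore be wider than the DMSO arrays alone would give. Of the 100 genes with the smallest p under FICZ, 80.2% had the same sign with KynA in split arrays, against a simulated mean of 49.1% and a highest value of 86.2%. Both values lie below the highest simulated ones, so what is left after the split may still be noise between arrays. A weaker response to KynA in the same direction as to FICZ also stays open.

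Regrouping asked how many splits of the 8 arrays gave as much as the real one. The splits took no account of the replicate numbers. Other splits mix arrays of both groups, so a treatment effect widens their spread and leaves them few gene calls. For FICZ against DMSO only the real split, 1 of 35, gave as many genes (92, highest other 0). The same held for lists (11, highest other 9) and for the AHR battery camera p (4.22e-07, smallest other 0.000223). A share of 1 of 35 is the smallest this test can give. It was not adjusted over the results tested, so chance is not excluded. The real list count was 8 under the stricter filter or without DMSO 2 and 9 without FICZ 4, where splits were not run. For KynA against DMSO 2 of 35 splits gave as many genes (1, highest other 1) and 7 gave as many lists (6, highest other 8). A battery camera p as small came from 2 splits (2.23e-06, smallest other 2.83e-07). For FICZ against KynA 4 of 35 splits gave as many genes (1, highest other 1). A battery camera p as small also came from 4 splits (0.000658, smallest other 3.31e-05). For lists only the real split, 1 of 35, gave as many (8, highest other 7), a margin of 1 list. The real count was itself 7 under cyclic loess, with array weights and without FICZ 2, FICZ 4, KynA 1 or KynA 4. For genes called with both ligands, 1 of 100 random groupings, the real one, gave as many (1; highest other 0), which decides nothing: 0 of the 99 others called a gene by limma in both comparisons, so their overlap was fixed at 0.

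Single arrays lay far from the other 3 of their group in 18 of the 276 groups of 4 examined, by the ratio of the gap to the range, where chance gives about 1 in 20. In DMSO arrays the ratios were 0.831 for COL6A5 (DMSO 2, 7.279 against 7.975 to 8.117), 0.854 for ID3 (DMSO 4, 8.772 against 8.201 to 8.284), 0.844 for SLC2A1 (DMSO 2), 0.87 for TPX2 (DMSO 1), 0.929 for CCNB2 (DMSO 4) and 0.841 for ASPM (DMSO 1). In FICZ arrays they were 0.842 for POGK (FICZ 1), 0.944 for TMEM119 (FICZ 4, 8.739 against 8.275 to 8.301), 0.838 for KDR (FICZ 3), 0.837 for ERG (FICZ 3), 0.906 for CSF3 (FICZ 2, 11.45 against 10.67 to 10.74) and 0.917 for ASPM (FICZ 4). In KynA arrays they were 0.859 for AHRR (KynA 2, 8.356 against 9.001 to 9.107), 0.836 for EREG (KynA 2), 0.84 for SLC2A1 (KynA 2), 0.866 for TPX2 (KynA 3), 0.905 for CENPE (KynA 1) and 0.919 for RPS23 (KynA 2).

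Transcript clusters without a symbol of their own, 1494 of which were tested, stood outside the comparisons. With FICZ against DMSO 6 of them passed, all higher, with KynA against DMSO 1 passed, and with FICZ against KynA 1 passed. A cluster with the symbols SERPINB2 and SERPINB10, 16852879, was 1.88 higher on the log2 scale with FICZ than with DMSO (limma adjusted p = 7.3e-06). It was 1.12 higher than with KynA (limma adjusted p = 0.00374). Which of these genes it measured cannot be told. An unnamed cluster, 16813856, was 1.09 higher on the log2 scale with FICZ (limma adjusted p = 3.5e-05) and 0.67 higher with KynA (0.0195).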

How the results depend on the processing

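No alternative in this part was added later. The cause of each change was not tested, except that leaving out arrays leaves fewer samples. For FICZ against DMSO the gene count of 92 became 140 (80 higher, 60 lower) with a trended, robust variance, 43 (36 and 7) with only the groups compared, and 42 to 103 leaving out 1 array. Cyclic loess gave 92 (71 and 21), centring 90 (69 and 21) and the stricter filter 107 (58 and 49). The KynA count of 1 became 2 with a trended, robust variance and 1 to 2 leaving out 1 array, and so did the count called with both ligands. The count for FICZ against KynA became 2 without a filter. With the replicate number as a block, KynA against DMSO, FICZ against KynA and both ligands gave 6 genes each, with CYP1B1, TIPARP, STC2, IL1B and CCL2 beside SLC16A6 for KynA (adjusted p 0.00737 to 0.0333), and FICZ against DMSO gave 124 (135 as a random effect). The labels do not say what samples with equal numbers share. Of 12 same-number pairs 6 correlated above 0.1, and 7 of 12 arrays correlated best with their own number. No chance value was computed for these counts, so an effect shared by equal numbers stays open. The main fit has no block and would not take such an effect out.

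With an estimated correlation 1 list was called in each comparison, against 11, 6 and 8. Fry called 7 for FICZ, 0 for KynA (366 genes at an unadjusted p under 0.05) and 2 between the ligands. With FICZ it did not call the hypoxia (adjusted p = 0.169), matrix (0.336), ribosomal (0.211) and myeloid (0.208) lists. With an estimated correlation, the AHR battery had an adjusted p of 0.127 with FICZ, 0.267 with KynA and 0.363 between them. By fry the battery had 0.00842 with FICZ, 0.317 with KynA and 0.416 between them. By camera at its preset correlation, the battery's adjusted p between the ligands ran from 0.000351 to 0.075 leaving out 1 array. KynA lists numbered 3 to 7 leaving out 1 array (3 without DMSO 3). Of 22 list calls other than those of the AHR battery, 3 were lost under cyclic loess, 2 without a filter, 4 of 20 under the stricter filter, 1 with a trended, robust variance, 2 with array weights and 1 with the block (endothelial markers in FICZ arrays, an adjusted p that rounds to 0.05). The correlation of the ligands' effects was 0.925 over genes changed by at least 1 ligand and 0.205 with DMSO arrays split. The genes behind the 0.925 were chosen by their difference from the same DMSO arrays. No simulation was run for that choice, so no conclusion is drawn from it.

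Values that changed sign did not pass under any setting. With KynA, NQO1 was 0.00108 under cyclic loess and −0.0821 to 0.124 leaving out 1 array, ALDH3A1 −0.0953 to 0.0961 and AHR −0.00815 to 0.0614. With FICZ, the endothelial gene FLT1 ran from −0.00588 to 0.243. Of 34 calls of named genes, 22 held in each of the 12 fits that left out 1 array, while 7 were lost without a filter, 4 with array weights, 11 with only the groups compared and 3 with the block. Signal over background limits what is seen of dim genes, which the table leaves out.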

Other observations

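The test of BMP-responsive genes in this part was chosen only after the values of ID1, ID2, BAMBI and SMAD6 were seen.

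Further genes rose with FICZ that fall outside the rule for named genes and were chosen after their values were seen. IGFBP4 rose by 0.97 ± 0.116 on the log2 scale (SE, n = 4; limma adjusted p = 0.00116) and IGFBP1 by 0.90 ± 0.121 (0.00234); both code for binding proteins of insulin-like growth factors. ALDH1A3, a retinaldehyde dehydrogenase, rose by 0.84 ± 0.103 (0.00116). GREM1, a secreted BMP antagonist, rose by 0.79 ± 0.0875 (0.000659). Each kept its call in 12 of 12 fits that left out 1 array.

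Several lists were not called with FICZ. None of 23 NRF2 targets passed (median −0.03; camera adjusted p = 0.877), nor any of 15 phase II conjugation genes (0.931), 10 tryptophan catabolism genes (0.719), 17 interferon response genes (0.877) or 16 amino acid transporter genes (0.055; 2 adjusted over the list alone). Of 22 TGF-beta targets 1 fell, ID3, and 4 fell adjusted over the list alone (0.304). The kynurenic acid receptor list had 3 tested members, too few for a test.

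GREM1 was higher and ID3, a BMP-responsive gene, lower in FICZ arrays, so lower BMP signalling may accompany FICZ, as a hypothesis. The other BMP-responsive genes tested were ID1 (−0.51), ID2 (−0.41), SMAD9 (−0.36), BAMBI (−0.66), SMAD6 (−0.11) and ATOH8 (0.04). Their mean difference was −0.337, with 5 of 6 genes lower and 4 of 4 FICZ arrays below the DMSO mean, and none of the 6 passed over all genes. The exact permutation p was 0.114, so the 8 arrays did not decide it.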
